A study of Mus musculus with 4 samples.

How the data were processed

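Single-cell transcriptomes of whole mouse embryonic trachea were analysed at 4 ages a day apart, the first E11.5 and the last E14.5, with 1 library per age. Per the labels' protocols, dissected tracheas were digested with trypsin and collagenase, with a digestion time given only as a range over all ages, and libraries were made with the 10x Genomics Chromium 3' kit. How many embryos went into each library is not given in the sources used here. The deposited values are UMI counts per gene and cell barcode, not normalized, per the file headers. Reads were processed with Cell Ranger 5.0.1 against mm10, per the submitters' processing notes, while the matrices name Cell Ranger 7.1.0, per the file headers. Whether intronic reads were counted is not given in the sources used here. The matrices list 32285 genes. A pooled matrix of the 4 libraries was not used, because no label ties its barcodes to ages.

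The classes, gene lists, comparisons, thresholds and most alternative settings were set before the data were examined, except where stated. Cells with 1000 or more genes and 10% or fewer mitochondrial counts were kept, which removed 298, 276, 389 and 362 barcodes for too few genes and 301, 302, 234 and 230 for mitochondrial counts in order of age. Scrublet was run per library as the doublet caller. Its automatic threshold marked 43 of 20587 cells, 0.209%, so the top-scoring cells of each library were removed as planned for that case, 842 in all. These counts overlap, since cells were scored for doublets before the other filters: 4879, 5057, 4405 and 4580 cells passed the gene and mitochondrial limits, and 4701, 4851, 4245 and 4451 remained after doublets were removed. The 18248 kept cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2, using 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 1.0, which gave 28 clusters. After a first clustering set dividing cells apart, 864 genes correlated with the cell cycle were left out of the variable genes. Clusters were named "X-like" from 16 sets of marker genes, requiring 3 detected markers. Details of the naming rule, including 2 clusters left unnamed for low UMI counts or mixed markers, were set after the clusters were seen. These unnamed clusters held 201, 92, 38 and 51 cells in order of age.

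Counts were summed over the cells of a class in each library and scaled to CPM over all genes. The log2 ratio of CPM plus 1 was taken between E14.5 and E11.5, with genes counted as 2-fold apart where the CPM was 20 or more in the higher library. A first count used the ratio without the added 1 and was corrected to the planned form. Folds are ratios of CPM without the added 1, with exact Poisson intervals, and shares have exact Clopper-Pearson intervals, all at 95%. A fold against 0 counts was computed against a floor of 3 counts over the class, and the limit for a share of 0 cells is 3 cells over the number of cells. Classes were compared where both libraries held 50 or more cells. No paired or replicated test was possible with 1 library per age.

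For each of 37 gene lists, the median log2 ratio was taken over members with a CPM of 5 or more and placed among 10000 random lists matched on mean expression in 20 bins. A median was counted as outside the random lists when it was at least 0.5 in size and at or beyond the 2.5 and 97.5 percentiles. A minimum of 5 measured members was added after values were seen. With it, 16 lists in the mesenchymal lineage, 14 in the epithelium and 13 in neural cells were counted, against 21, 19 and 14 without it. Share differences were counted as having a direction only where their interval excluded 0, also a later choice.

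Genes were named by a fixed rule: in each main class the 12 with the highest and the 12 with the lowest log2 ratio among genes with a CPM of 20 or more, the same direction between E12.5 and E13.5, and a CPM of at least 0.1 of that in every other class. Globins, mitochondrial and ribosomal protein genes, Xist, Y-linked and unnamed transcripts were left out. Neural cells had 4 genes in each direction, and members of the gene lists were also named. To compare shares of cells with a UMI, cells were thinned to 5000 UMIs, which left out 89, 48, 43 and 44 mesenchymal and 33, 26, 14 and 31 epithelial cells with fewer. Free RNA was judged from pooled endothelium- and macrophage-like cells. Gene positions are on GRCm38 (mm10), counted from 1.

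The calculations were tested on simulated counts drawn from the real class means. In the mesenchymal lineage, 100.0% of 50 genes made 3-fold higher and 100.0% of 50 made 3-fold lower were called 2-fold apart, and 0% of 7165 unchanged genes. In the epithelium these were 100.0%, 94.0% and 0% of 6943. The simulated counts held Poisson error only, with no variation between libraries, and genes were called on the ratio without the added 1. The simulation therefore gives no rate of false calls for a design with 1 library per age. Alternatives covered cell filters, doublets, clustering resolution, classing of single cells, scaling, aggregation, pseudocount, gene filter, thinning depth and the ages compared. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.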

Results

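Whole tracheas of mouse embryos were profiled by single-cell RNA sequencing at 4 ages, embryonic days (E) 11.5, 12.5, 13.5 and 14.5, with 1 droplet library per age. Over these days the tracheal tube lengthens, its cartilage and smooth muscle form in the mesenchyme, and its epithelium begins to make basal and secretory cells. The deposited matrices held 5323, 5456, 4934 and 5091 cell barcodes in order of age, with 110819223, 116305122, 101289410 and 100822345 unique molecular identifier (UMI) counts. After filtering, 4701, 4851, 4245 and 4451 cells were kept, with median UMI counts of 20661, 20897, 20808 and 19300. Each age is a single library, so age and library cannot be separated, no difference has a replicate check, and no test was made. Intervals in parentheses are exact 95% intervals and cover counting error only.

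By cluster, mesenchyme was the largest part of the kept cells at all 4 ages, and the E14.5 library held a larger share of epithelium than the E11.5 library. Epithelium-like cells made up 11.1% of kept cells at E11.5 (10.2 to 12.02), 17.1% at E12.5 (16.1 to 18.2), 19.95% at E13.5 (18.8 to 21.2) and 25.9% at E14.5 (24.6 to 27.2). Cells of the mesenchymal lineage, the union of mesenchyme-, chondrogenic-, smooth muscle- and pericyte-like clusters, made up 75.5%, 73.8%, 74.2% and 70.6%. With each cell classed by its own markers the lineage made up 44.3% at E11.5, and with the stricter cell filter 47.4% at E13.5. Endothelium-like cells made up 2.70% at E11.5 (2.26 to 3.21) and 0.652% at E14.5 (0.437 to 0.934). Neural cells, glia- and neuron-like together, made up 2.28%, 3.09%, 2.21% and 1.17%, and macrophage-like cells between 0.289% and 0.539%. Skeletal muscle-like cells made up 1.17%, 2.08% and 1.39% in the first 3 libraries, while the E14.5 library held 0 of 4451 cells, which allows a share of up to 0.067%. Mesothelium-like cells numbered 82 at E11.5 and 4 at both E12.5 and E13.5, and 0 of 4451 cells were found at E14.5. Classing each cell by its own markers instead gave neural shares of 8.105% at E11.5 and 1.80% at E14.5, endothelial shares of 4.34% and 0.966%, macrophage shares of 1.19% and 0.854% and erythroid shares of 7.51% and 1.21%. It also put 18 skeletal muscle-like cells (0.404%) and 97 mesothelium-like cells (2.18%) in the E14.5 library. Calls on single cells are uncertain. Over all libraries they moved 489 cells of mesenchyme-like clusters to cardiac muscle and 347 to megakaryocyte. They also moved 100 cells of epithelium-like clusters to mesothelium, whose marker set shares Krt19 with that of epithelium. Erythroid-like cells numbered 38, 24, 1 and 1, a number set by the minimum of 1000 genes per cell: with 200 as the minimum they numbered 38, 36, 20 and 71, or 0.751% at E11.5 (0.532 to 1.03) and 1.47% at E14.5 (1.15 to 1.85), so no direction was read from them. Clusters left unnamed held 4.28%, 1.90%, 0.895% and 1.15%. The direction of the mesenchymal difference depended on the processing: the E14.5 minus E11.5 difference of -4.93 percentage points became 18.9 points when each cell was classed by its own markers and 7.02 points with no doublets removed. The epithelial difference of 14.8 points kept its direction under every alternative but became 6.51 points with a stricter cell filter.

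**Figure D1:**
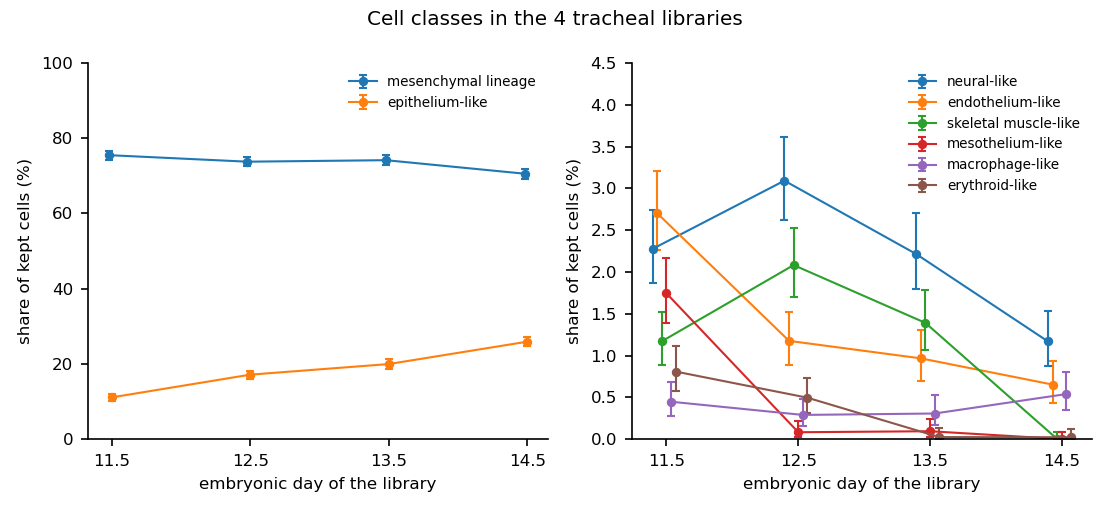
Share of kept cells (%, vertical axis) against the embryonic day of the library (horizontal axis), for the mesenchymal lineage and epithelium (left) and for 6 smaller classes (right). Points are single libraries and bars are exact 95% intervals for counting error. The epithelium-like share is 11.1% at E11.5 and 25.9% at E14.5.

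In the mesenchymal lineage, genes of the cartilage and connective tissue matrix were higher in the E14.5 library than in the E11.5 library, and 7 of 14 measured regulators of the early tracheal mesenchyme were at least 2-fold lower. All 11 measured members of the chondrogenic matrix list were at least 2-fold higher, with a median log2 ratio of 2.57. Acan, which encodes the cartilage proteoglycan aggrecan, was at 0.117 CPM (counts scaled to the total of the class) at E11.5 and 54.7 CPM at E14.5, 469-fold higher (247 to 1026). In mesenchymal clusters with a Tbx4 CPM of 30 or more, which leave out 6 clusters, the chondrogenic-like cluster 9 among them, the list median was 0.12 and the log2 ratio of Acan 1.15 instead of 5.64. Col2a1, the main cartilage collagen, was at 83.3 and 351 CPM, 4.21-fold higher (4.09 to 4.33). Col11a2 was 35.8-fold higher (27.8 to 47.1), and Cnmd, which encodes chondromodulin, 51.2-fold higher (38.5 to 69.4). The fibrillar and elastic matrix list had 17 of 23 members at least 2-fold higher, 6 between and 0 lower, with a median of 1.73. Among these, the elastin gene Eln was at 24.4 CPM at E11.5 and 547 CPM at E14.5, 22.4-fold higher (21.4 to 23.5), Postn was 39.3-fold higher (35.7 to 43.4), and Col1a1 3.32-fold higher (3.27 to 3.36). Both medians lay above every one of 10000 random lists of the same size and expression, as a description of these libraries. Markers of another cell type were also higher in the lineage, since epithelial junction and keratin genes had a median of 0.92, with 2 of 5 at least 2-fold higher, 3 between and 0 lower. That median turned to -0.70 for members with a CPM of 20 or more, -0.88 with the other classes subtracted and -0.02 for E13.5 against E11.5. Some lists named for other cell types were lower in the lineage. Respiratory epithelial regulators had a median of -0.825, with 3 of 7 at least 2-fold lower, 4 between and 0 higher. Irx1 and Irx2 belong to this list but passed the limit against other classes in the lineage, so the list does not mark epithelium alone. Neuronal differentiation genes had a median of -1.35, with 3 of 5 lower, 2 between and 0 higher.

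Different clusters held the lineage at the 2 ages. At E11.5 most of its cells were in clusters 6, 8, 13 (pericyte-like), 7 and 16 (smooth muscle-like), with 993, 823, 552, 531 and 327 cells. At E14.5 they were mainly in clusters 2, 9 (chondrogenic-like) and 12, with 1421, 718 and 695 cells. Of 7895 genes with a CPM of 20 or more in either library, 382 were at least 2-fold higher at E14.5 and 370 at least 2-fold lower. Between E12.5 and E13.5, a pair that shares no library with the first, 294 of the 382 and 352 of the 370 lay in the same direction. The share of all genes lying each way in this pair is not given here, so the match has no background. Its 2-fold genes leaned downward, with 57 higher and 89 lower. Scaling by trimmed mean of M values (TMM), which shifts log2 ratios by 0.17 in this lineage and 0.09 in the epithelium, gave 494 higher and 246 lower genes. Without the E14.5 library, E13.5 against E11.5 gave 171 higher and 193 lower genes, and without the E11.5 library, E14.5 against E12.5 gave 220 and 232.

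Among single genes, the largest log2 ratio in the lineage was that of Ecrg4 (ENSMUSG00000026051, chromosome 1, 43730602 to 43742578 on mm10), at 0.675 CPM at E11.5, 36.3 at E12.5, 343 at E13.5 and 971 at E14.5, 1439-fold higher at the last age than at the first (1097 to 1927). Next were Mia, 399-fold higher (284 to 579), and Wif1, a secreted Wnt inhibitor, at 2.80 CPM at E11.5 and 345 CPM at E14.5, 123-fold higher (108 to 142). The small leucine-rich proteoglycans Aspn and Ogn were 80.3-fold (69.1 to 93.9) and 40.2-fold higher (37.5 to 43.1). Cytl1, Agtr2 (the angiotensin type 2 receptor gene), Fibin, Sim2, Mannr and Tm4sf1 completed the genes named by the rule, between 52.7-fold and 494-fold higher. In the mesenchymal clusters with a Tbx4 CPM of 30 or more, the log2 ratio of Cytl1 was 3.01 instead of 5.997, that of Wif1 5.16 instead of 6.51 and that of Mia 5.53 instead of 6.91. At the other end, the homeobox gene Irx1 (ENSMUSG00000060969, chromosome 13, 71957921 to 71963723) was at 54.0, 24.3, 5.53 and 0.238 CPM, 226-fold lower at E14.5 than at E11.5 (137 to 405). Irx2 was 51.0-fold lower (37.8 to 70.7) and Zfp536 65.3-fold lower (52.7 to 82.0). The neuropeptide gene Gal was 124-fold lower (78.0 to 209), the chromatin remodeller gene Chd7 26.6-fold lower (23.1 to 30.7), and the transcription factor gene Six2 42.0-fold lower (29.8 to 61.1). Itga4 and Clca3a1, 34.8-fold and 60.7-fold lower, are leading genes of the pericyte-like cluster 13, of which the E11.5 library gave 552 cells. Msc, Hsd11b2, Tll1 and Rprm, between 17.9-fold and 83.8-fold lower, were the others.

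**Figure D2:**
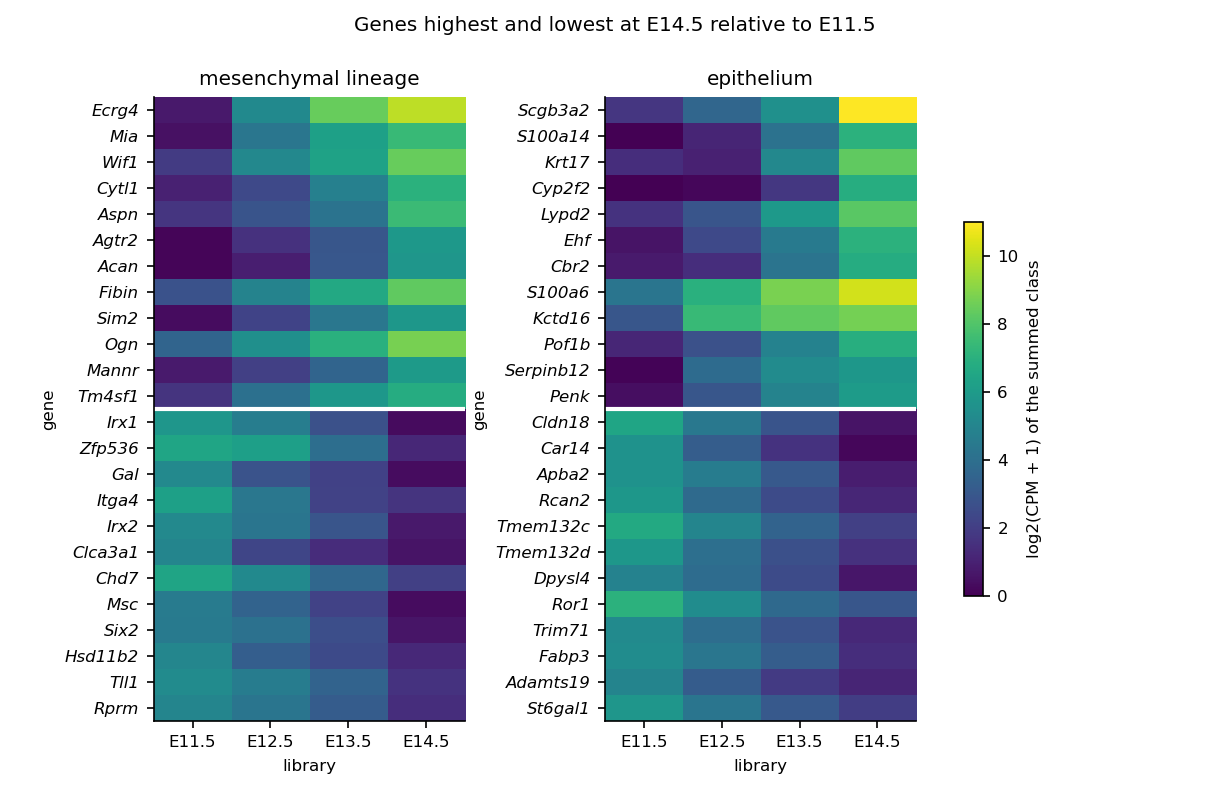
Heat maps of log2(CPM + 1) of the summed counts (colour scale) for the 12 genes furthest above and the 12 furthest below a ratio of 1 at E14.5 relative to E11.5 (vertical axis) in the 4 libraries (horizontal axis), for the mesenchymal lineage (left) and the epithelium (right). Scgb3a2 in the epithelium goes from 2.39 CPM at E11.5 to 2035 CPM at E14.5, and Irx1 in the mesenchymal lineage from 54.0 to 0.238 CPM.

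The list of tracheal mesenchyme regulators had 7 of 14 measured members at least 2-fold lower at E14.5, 3 at least 2-fold higher and 4 between, with a median log2 ratio of -0.999. Tbx4 and Tbx5, T-box genes of the respiratory mesenchyme, were at 70.7 and 130 CPM at E11.5 and at 34.6 and 58.8 CPM at E14.5, 2.04-fold (1.94 to 2.15) and 2.22-fold lower (2.13 to 2.30). Both lie near the 2-fold limit, and the TMM shift of 0.17 in log2 ratio would bring them under it. Foxf1 was 3.497-fold lower (3.31 to 3.70) and the Wnt agonist gene Rspo2 6.83-fold lower (6.46 to 7.23). Osr2, Barx1 and Fgf10 went the other way, with Osr2 at 3.63 and 80.9 CPM, 22.3-fold higher (19.8 to 25.2). Of 7 Hedgehog targets, 4 were at least 2-fold lower and 0 higher, with a median of -1.10. Foxf1 and Foxf2 belong to both lists, and the direct Hedgehog readouts Gli1 and Ptch1 were only 1.12-fold (1.04 to 1.21) and 1.25-fold lower (1.22 to 1.29). Members of the retinoic acid pathway went both ways, with a median of -0.91. Aldh1a2, which makes retinoic acid, was 13.7-fold lower (12.2 to 15.6) but low against another class, while Cyp26b1, which degrades it, was 2.98-fold higher (2.57 to 3.45). Of 10 Wnt targets, 3 were lower, 3 higher and 4 between: Lef1 was 2.30-fold lower (2.15 to 2.45) and Axin2 1.77-fold lower (1.64 to 1.92), against higher Wif1, Lgr5 and Notum. The list's median was -0.64 and its mean 0.49, which differ in sign. With the median of the other classes subtracted, the medians of the retinoic acid list and the Wnt targets turned to 1.72 and 0.48.

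Regulators of cartilage did not follow the matrix genes. The chondrogenic regulator list had a median of -0.53, with 1 of 7 members at least 2-fold higher, 1 lower and 5 between. Sox9, the master regulator of chondrocytes, was at 331 CPM at E11.5, 427 at E12.5, 329 at E13.5 and 229 at E14.5, 1.45-fold lower at the last age than at the first (1.42 to 1.48). After each cell was thinned to 5000 UMIs, a Sox9 UMI was found in 58.8% (57.2 to 60.5), 66.7%, 61.9% and 47.8% (46.0 to 49.5) of mesenchymal cells, and in 2.90% and 1.89% of pooled endothelium- and macrophage-like cells at the first and last age. Without thinning the Sox9 shares at these ages were 80.8% and 71.1%. An Acan UMI was found in 0.029% (0.001 to 0.161), 0.680%, 2.61% and 10.8% (9.74 to 11.96) of thinned mesenchymal cells, 0.197% and 17.7% without thinning at the first and last age, against 1.89% of thinned endothelium- and macrophage-like cells at E14.5. Median depths were 20485 and 18785 UMIs in the lineage and 22297 and 25616 in the background cells at E11.5 and E14.5. A Tbx4 UMI was found in 26.2% (24.7 to 27.7) and 14.2% (13.03 to 15.5) of thinned mesenchymal cells at E11.5 and E14.5, with 0.725% and 0% of background cells.

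Contractile genes of smooth muscle had a median log2 ratio of 0.28, with 2 of 17 members at least 2-fold higher, 2 lower and 13 between. Acta2 was at 403, 645, 654 and 490 CPM, Actg2 at 74.4 and 119 CPM at the first and last age, and the regulator gene Myocd was 4.29-fold lower at E14.5 (3.98 to 4.62). Smooth muscle-like cells were in cluster 16 at E11.5 and mainly in cluster 14 later. The share of cells with an Acta2 UMI was 21.9% at E11.5 and 8.14% at E14.5, while the CPM was higher at E14.5. Smooth muscle-like cells made up 7.23% of kept cells at E11.5 and 2.52% at E14.5, so share and CPM need not conflict. No order was read from the Acta2 values.

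In the epithelium, basal and secretory cell genes were higher in the E14.5 library than in the E11.5 library, and several Wnt target genes and respiratory transcription factor genes were lower. The basal list had 8 of 9 measured members at least 2-fold higher and 1 between, with a median log2 ratio of 2.52, and the secretory list 5 of 7 higher and 2 between, with a median of 2.78. The secretory median depended on the setting, from 1.26 with a pseudocount of 5 CPM and 1.48 with no filter on members to 4.20 with the stricter cell filter and 6.73 for members with a CPM of 20 or more. Markers of another cell type were also higher in the epithelium, since 9 of 16 fibrillar and elastic matrix genes were at least 2-fold higher, 2 lower and 5 between, with a median of 1.16. That median turned to -0.52 with each cell classed by its own markers, -0.63 with the other classes subtracted and -0.19 for E13.5 against E11.5. Oesophageal and pharyngeal epithelium genes also had a higher median, 2.10, with 3 of 5 at least 2-fold higher and 2 lower. Their median was -0.044 for E13.5 against E11.5. Scgb3a2 (ENSMUSG00000038791, chromosome 18, 43764289 to 43767399), which encodes a secretoglobin of airway secretory cells, was at 2.39 CPM at E11.5, 11.3 at E12.5, 45.1 at E13.5 and 2035 at E14.5, 853-fold higher at the last age than at the first (597 to 1264). Krt17 and Krt15, keratins of basal cells, were 184-fold (121 to 294) and 35.1-fold higher (28.2 to 44.2). Trp63, the basal cell transcription factor gene, was at 16.1, 23.3, 52.8 and 89.2 CPM, 5.53-fold higher (4.79 to 6.41). Cyp2f2, a cytochrome P450 gene of secretory cells, had 0 counts at E11.5 and 116.3 CPM at E14.5. It was 487-fold higher against a floor of 3 counts, with an exact lower bound of 396.

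The epithelium at E11.5 was mostly cluster 15 (451 cells), at E12.5 and E13.5 cluster 3 (737 and 643 cells) and at E14.5 cluster 4 (1138 cells). A small cluster, number 27, with Foxe1 and Pitx1 among its leading genes held 21, 16, 1 and 0 cells. Of 7842 genes with a CPM of 20 or more in either library, 659 were at least 2-fold higher at E14.5 and 427 at least 2-fold lower. Between E12.5 and E13.5, 587 and 408 of these lay in the same direction. The share of all genes lying each way in that pair is not given here, and its 2-fold genes were 79 higher and 25 lower. Without the E14.5 library, E13.5 against E11.5 gave 252 higher and 222 lower genes, and without the E11.5 library, E14.5 against E12.5 gave 384 and 196. The early response genes induced by cell dissociation were higher in the same direction, with a median log2 ratio of 2.31 in the epithelium and 0.81 in the mesenchymal lineage. The mesenchymal median turned to -0.29 for E14.5 against E12.5 and to -0.68 with the median of the other classes subtracted.

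Besides Scgb3a2, Krt17 and Cyp2f2, the rule named S100a14 and Lypd2, the latter 142-fold higher (96.9 to 218). S100a14 had 0 counts at E11.5 and was 558-fold higher at E14.5 against a floor of 3 counts, with an exact lower bound of 454. The epithelial transcription factor gene Ehf was 276-fold higher (126 to 751) and the calcium-binding protein gene S100a6 66.6-fold higher (58.5 to 76.1). Serpinb12 had 1 count at E11.5 and a ratio of 693 (124 to 27401), and the enkephalin precursor gene Penk was 204-fold higher (79.6 to 750). Cbr2, Kctd16 and Pof1b were between 63.0-fold and 155-fold higher. Cldn18 (ENSMUSG00000032473, chromosome 9, 99689461 to 99717267), which encodes a tight-junction claudin, was at 87.7, 20.2, 6.22 and 0.500 CPM, 175-fold lower at E14.5 than at E11.5 (104 to 322). The carbonic anhydrase gene Car14 was 335-fold lower (130 to 1233), and Ror1, a Wnt5a receptor gene, 20.2-fold lower (17.3 to 23.6). Trim71, a let-7 target gene, was 26.5-fold lower (19.1 to 37.8). Apba2, Rcan2, Tmem132c, Tmem132d, Dpysl4, Fabp3, Adamts19 and St6gal1 were between 18.1-fold and 55.7-fold lower.

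Of 10 measured Wnt targets in the epithelium, 6 were at least 2-fold lower at E14.5, 2 higher and 2 between, with a median log2 ratio of -1.34. Axin2 was at 12.97 and 1.82 CPM, 7.11-fold lower (5.16 to 9.94), Lef1 was 5.03-fold lower (4.23 to 5.99) and Sp5 52.3-fold lower (26.0 to 123). Apcdd1 went the other way, 8.41-fold higher (6.12 to 11.9). Wnt ligands and secretion genes went both ways, with 3 of 10 at least 2-fold higher, 2 lower and 5 between, and a median of -0.47. The 16 respiratory epithelial regulators had a median of -0.86, with 7 at least 2-fold lower, 2 higher and 7 between, which turned to 0.45 with the median of the other classes subtracted. Nkx2-1, which specifies the respiratory epithelium, was at 223, 182, 151 and 125 CPM, 1.78-fold lower (1.69 to 1.87), Foxp2 was 3.10-fold lower (3.01 to 3.18) and Foxa2 2.35-fold lower (2.21 to 2.49). Klf5 was at 41.9 and 638 CPM, 15.2-fold higher (13.96 to 16.6), and Elf3 was 4.59-fold higher (3.73 to 5.71). Of 8 FGF targets, 6 were at least 2-fold higher, 1 lower and 1 between, with a median of 1.18: Dusp6 was 3.82-fold higher (3.32 to 4.41) and Etv4 28.0-fold higher (14.6 to 61.6), while Etv5 was 2.49-fold lower (2.21 to 2.79). Junction and keratin genes had a median of 0.92, or -0.44 with the other classes subtracted, with Krt19 28.2-fold higher (25.5 to 31.3). Distal lung genes had 4 of 5 members at least 2-fold lower, with a median of -1.27.

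After thinning to 5000 UMIs, a Trp63 UMI was found in 4.10% (2.52 to 6.26), 9.56%, 20.9% and 28.7% (26.1 to 31.4) of epithelial cells, and in 0% of pooled endothelium- and macrophage-like cells at E11.5 and E14.5. Without thinning the shares at the first and last age were 10.9% and 55.3%. A Scgb3a2 UMI was found in 0.820% (0.224 to 2.08), 3.73%, 9.48% and 56.4% (53.5 to 59.3) of thinned epithelial cells, with 3.77% (0.460 to 12.98) of background cells at E14.5. Unthinned, these were 1.54% and 71.1% at the first and last age, with 22.6% of background cells at E14.5. A Sox2 UMI was found in 65.8% (61.4 to 70.0) and 82.5% (80.2 to 84.7), and a Nkx2-1 UMI in 64.8% (60.3 to 69.0) and 44.0% (41.1 to 47.0). Of thinned background cells, 0.725% at E11.5 and 0% at E14.5 held a Sox2 UMI, and the background for Nkx2-1 is not given here. Krt5, a keratin of mature basal cells, was found in 2.67% (1.81 to 3.79) at E14.5, and Foxj1, of multiciliated cells, in 1.25% (0.684 to 2.08), against 0 of 53 background cells, which allows a share of up to 5.66%. The multiciliated list had a median log2 ratio of 0.13, with 6 of 8 members between the thresholds. Only 1 neuroendocrine gene was measured in the epithelium, while the neural class had more, as given below. Median depths at E11.5 and E14.5 were 23750 and 21343 UMIs in the epithelium.

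**Figure D3:**
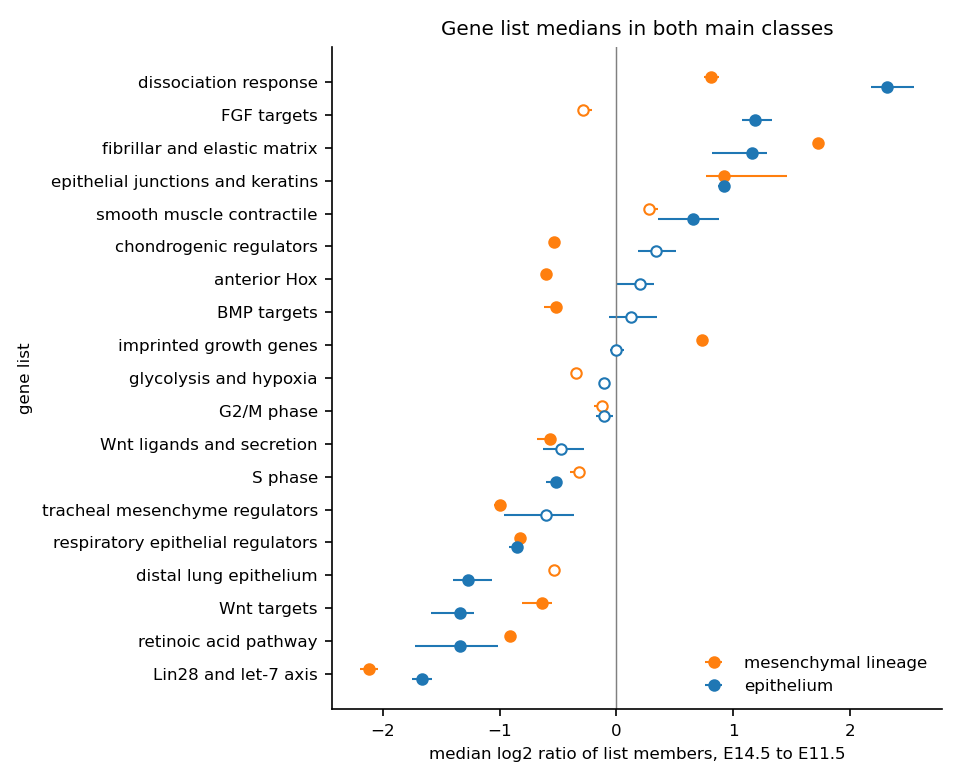
Median log2 ratio of list members at E14.5 relative to E11.5 (horizontal axis) for each gene list with 5 or more measured members in both classes (vertical axis), for the mesenchymal lineage and the epithelium. Filled points have a median of at least 0.5 in size and outside the central 95% of random lists, and bars are 95% ranges from Poisson resampling of the counts. The Lin28 and let-7 list is lowest in both classes, at -2.12 and -1.66.

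Neural cells were compared as 1 class of 107 cells at E11.5 and 52 at E14.5, and genes of mature neurons were higher in the later library. The neuronal differentiation list had 9 of 11 members at least 2-fold higher, with a median log2 ratio of 2.06: Stmn2 was 43.4-fold higher (37.9 to 49.9) and the neurofilament gene Nefl 18.1-fold higher (14.4 to 23.2). S-phase genes had a median of -1.57, with 15 of 17 at least 2-fold lower. Neuroendocrine genes, of which 8 were measured here, had a median of 2.66, with 6 at least 2-fold higher, 1 lower and 1 between. At a clustering resolution of 0.5, 15 neuron-like cells were classed as epithelium. Epithelial junction and keratin genes, markers of another cell type, were also higher in the neural class, 6 of 8 by at least 2-fold, with a median of 1.77. Respiratory epithelial regulators went the other way there, with a median of -1.35, 3 of 6 at least 2-fold lower, 1 higher and 2 between. The adhesion gene Cntn5 was 1270-fold higher (495 to 4665) from 4 counts at E11.5, and Prph, which encodes peripherin, 207-fold higher (118 to 402). Gabrg3 and Atp1b1 had 0 counts at E11.5 and were 170.0-fold and 160.2-fold higher against a floor of 3 counts. Their exact lower bounds were 137 and 129. Cck and Hsd11b2 had 0 counts at E14.5, 39.7-fold and 13.4-fold lower against the same floor, with exact lower bounds of 32.0 and 10.7. Dkk2 and Dct were 29.9-fold (15.6 to 65.7) and 39.2-fold lower (6.85 to 1567). The mix of the class differed, since the glia-like cluster 20 held 86 and 27 of its cells at these ages and the neuron-like cluster 22 held 21 and 25. In all, 1059 of 8490 genes were at least 2-fold higher and 899 lower. Endothelium-, macrophage-, skeletal muscle- and erythroid-like cells numbered fewer than 50 in at least 1 of the libraries compared and were not compared.

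Between neighbouring ages, the mesenchymal lineage had 186 genes at least 2-fold apart from E11.5 to E12.5, 146 from E12.5 to E13.5 and 174 from E13.5 to E14.5. The epithelium had 209, 104 and 268. Over all 4 libraries, 8.83% of mesenchymal genes were ordered upward with age and 24.1% downward, and in the epithelium 15.0% and 24.8%. A random order gives 4.17% each way, but genes share the shifts of their library, so this is no value for an absence of differences. The balance between the directions depends on the scaling, since the median log2 ratio on CPM was itself -0.17 in the lineage and -0.11 in the epithelium.

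Globin genes, which pass from embryonic to adult forms over these days, served as a check of the age labels. Embryonic globins (Hba-x, Hbb-bh1 and Hbb-y) made up 80.2% of globin counts in 38 erythroid-like cells at E11.5 and 64.8% in 24 cells at E12.5. The E13.5 and E14.5 libraries held 1 such cell each, at 0.0059% and 72.6%. Over all deposited barcodes the embryonic share was 79.7%, 59.3%, 16.8% and 7.04%.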

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

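The tests of handling that acted on all classes alike and of handling in the E11.5 library alone were chosen after the result they measure was seen, and the other tests before, although the setting of the Tbx4 clusters was added after the data were seen.

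Barcodes with under 1000 genes, which the cell filter removes, included some with at least 0.5 of their UMIs from globins. There were 11 at E12.5, 18 at E13.5 and 82 at E14.5, 1.61% of the barcodes of that library, and 0 at E11.5. They stood out as a signal in data that the comparisons leave out. No biological explanation was tested for them.

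The step from E13.5 to E14.5 held the most 2-fold genes of the epithelium, 268 against 209 and 104 in the steps before. After the mesenchymal lineage's log2 ratio of the same step was subtracted, 56.7% of them (50.6 to 62.7) stayed 2-fold apart. This argues against a shift of the E14.5 library of equal size in both classes as the whole cause. Genes with few counts in the mesenchymal lineage stay apart after subtraction whatever the cause, so a shift of unequal size stays open. A shared part remains, since the log2 ratios of the 2 classes correlated at 0.55 in this step, against 0.40 and 0.57 in the steps before, where 58.4% and 45.2% of the genes stayed. The sex mix differed between the libraries, with a Y-linked UMI in 54.8% of thinned cells at E13.5 and 0.046% at E14.5. Only 5.22% of the genes lay on the X or Y chromosome, against 3.49% of measured genes. With so few measured genes there, the test could hardly have placed most of the 2-fold genes on them. It also leaves out effects of sex on genes of other chromosomes, so the sex mix stays open as a cause. A library effect confined to the epithelium stays open, and so does age, which the design cannot separate from the library.

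Genes of the mesenchymal lineage 2-fold lower at E14.5 were tested against a difference in the regions dissected. Clusters with a Tbx4 CPM under 30 held 38.9% of mesenchymal cells at E11.5 and 26.5% at E14.5, but 718 of these 833 cells at E14.5 were chondrogenic-like cluster 9, which held 0 at E11.5, so the shares understate the difference in other clusters, and Tbx4 itself was 2.04-fold lower at E14.5, so a fixed limit does not select like cells at both ages. Between cells of the remaining clusters, 82.4% of the 370 lower genes (78.2 to 86.2) stayed 2-fold lower. Most of these differences therefore did not rest on the clusters left out. The sampling of regions stays open, because the limit does not select like cells and the genes were chosen in the whole lineage. Single genes depended more on the clusters left out. The log2 ratio of Irx1 was -5.47 in the whole lineage and -2.37 in the remaining clusters, and that of Irx2 -4.41 and -1.63. Age and other library effects stay open.

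The dissociation response list was higher at E14.5 than at E11.5, by a median log2 ratio of 2.31 in the epithelium, 0.81 in the mesenchymal lineage and 0.42 in neural cells. The unequal medians argue only against handling that raised the list by the same amount in every class. Handling shared by the classes, with responses of unequal size, stays open. Between E13.5 and E11.5 the median in the epithelium was already 1.99, which argues against a handling difference in the E14.5 library alone. A handling difference in the E11.5 library alone cannot be told apart from age. The medians of E12.5 against E11.5 were 1.57 in the epithelium, 0.95 in the mesenchymal lineage and 0.72, the lowest, in neural cells. Those of E14.5 against E12.5 were 0.86, -0.29 and -0.56, higher in the epithelium only. In size they were 0.547, 0.302 and 0.781 times as large, where the test needed all under 0.5. Read with sign, only the epithelium missed this limit. Read by size, neural cells missed it as well. Fos, at 79.5 and 814 CPM in the epithelium at E11.5 and E14.5, and Junb, 13.03-fold higher, were among its members.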

How the results depend on the processing

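No paired analysis was possible because each age is 1 library. Settings added after seeing the data were E13.5 against E11.5, E14.5 against E12.5, the Tbx4 clusters and leaving out cells with under 1% mitochondrial counts. No list median counted as outside the random lists reversed at clustering resolutions of 0.5 and 2 or with 200 genes as the minimum. None reversed without globin, mitochondrial and ribosomal protein genes in the CPM. Gene counts cannot reverse, and here they stayed within 1.5-fold of the main counts. At a resolution of 0.5 the mesenchymal lineage held 3549 and 3141 cells at E11.5 and E14.5, as in the main setting. That setting could therefore hardly move its results. With 200 genes as the minimum, the erythroid-like share was higher at E14.5 (1.47%) than at E11.5 (0.751%). Except where stated, the cause of a difference was not tested.

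The E14.5 minus E11.5 share of the mesenchymal lineage, -4.93 points, was 18.9 with each cell classed by its own markers, 0.397 with the strict filter of 2500 genes and 5% mitochondrial counts, 7.02 with no doublets removed and -8.31 without cells under 1% mitochondrial counts. Classing by single-cell markers moved 489 mesenchyme-like cells to cardiac muscle and 580 to neuron, among other classes. With no doublets removed, 589 pericyte-like and 90 mesothelium-like cells fell in an unnamed cluster, and with the strict filter 1142 mesenchyme-like cells fell in unnamed clusters. The epithelial 14.8 points were 9.38 by single-cell markers and 6.51 with the strict filter.

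The counts of higher and lower genes, 382 and 370 in the mesenchymal lineage and 659 and 427 in the epithelium, follow the minimum CPM by construction: 623, 681, 1138 and 767 at 5 and 240.0, 177, 353 and 206 at 50. E13.5 against E12.5 gave 57, 89, 79 and 25, E13.5 against E11.5 gave 171, 193, 252 and 222, and E14.5 against E12.5 gave 220.0, 232, 384 and 196. TMM gave 246 lower genes in the mesenchymal lineage.

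The chondrogenic matrix median of 2.57 was 2.36 by single-cell markers, 2.78 with the strict filter, 2.34 with no doublets removed, 2.40 from each cell's mean CPM, 2.74 with TMM, 2.19 with a pseudocount of 5, 2.02 with no filter on members and 2.86 with the other classes' median subtracted. It was 0.12 in the Tbx4 clusters, which leave out chondrogenic-like cluster 9 and 5 other clusters. The smooth muscle median of 0.28 was -0.013 by single-cell markers, 0.12 with the strict filter, 0.25 in the Tbx4 clusters, -0.066 by mean CPM, 0.45 with TMM, 0.36 at a CPM of 20 and -0.002 after subtraction. The basal median of 2.52 was 2.16 with a pseudocount of 5, 2.06 with no filter and 1.76 after subtraction. The secretory median of 2.78 was 4.20 with the strict filter, 1.26 with a pseudocount of 5, 1.48 with no filter and 6.73 at a CPM of 20. For the chondrogenic, smooth muscle, basal and secretory lists, E13.5 against E12.5 gave 0.38, -0.046, 1.03 and 1.01, E13.5 against E11.5 gave 2.38, 0.57, 1.65 and 2.08, and E14.5 against E12.5 gave 1.09, -0.38 and 2.17 for the first 3. The embryonic globin shares of 80.2% and 64.8% were 79.7% and 59.3% over all barcodes.

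Other list medians reversed. After subtraction, in the mesenchymal lineage, anterior Hox was 0.25, Wnt ligands 0.13, Wnt targets 0.48, retinoic acid 1.72, dissociation -0.68 and junctions -0.88. In the epithelium, fibrillar matrix was -0.63, retinoic acid 0.62, S phase 0.44, Lin28 0.015, respiratory regulators 0.45 and junctions -0.44. E13.5 against E12.5 gave -0.13 for dissociation and -0.60 for junctions in the mesenchymal lineage, and -0.04 for smooth muscle and -0.31 for fibrillar matrix in the epithelium. E13.5 against E11.5 gave -0.02 for mesenchymal junctions and -0.19 for epithelial fibrillar matrix. For oesophageal and pharyngeal genes in the epithelium it gave -0.044, against 2.10 for E14.5 against E11.5. E14.5 against E12.5 gave -0.29 for mesenchymal dissociation. Mesenchymal junctions were -0.70 at a CPM of 20, and by single-cell markers epithelial smooth muscle was -0.95 and fibrillar matrix -0.52.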

Other observations

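Genes of the Lin28 and let-7 axis, which times development in many tissues, had medians lower in the E14.5 library than in the E11.5 library in all 3 classes compared. The list's median log2 ratio was -2.12 in the mesenchymal lineage, with 7 of 8 members at least 2-fold lower, -1.66 in the epithelium, with 6 of 8, and -1.27 in neural cells, with 4 of 8, and all others lay between. With the median of the other classes subtracted, the epithelial median was 0.015, so the difference in the epithelium cannot be separated from one of the whole library. Lin28b, which blocks let-7 maturation, was at 44.1 and 3.97 CPM in the mesenchymal lineage, 11.1-fold lower (9.75 to 12.7), and 5.50-fold lower (4.54 to 6.71) in the epithelium. The let-7 target gene Hmga2 was 4.53-fold (4.45 to 4.62), 2.66-fold (2.55 to 2.78) and 14.2-fold lower (10.95 to 18.6) in the 3 classes. Mycn was 17.1-fold (12.6 to 23.5) and 7.70-fold lower (6.87 to 8.65) in the first 2.

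Imprinted growth genes, many of which control fetal growth, were compared across the 3 classes. Their median log2 ratio was 0.73 in the mesenchymal lineage, with 5 of 11 at least 2-fold higher, 6 between and 0 lower, and 0.73 in neural cells, with 3 higher, 3 lower and 5 between. In the epithelium it was 0.00, with 2 higher, 2 lower and 7 between. Igf2, a fetal growth factor gene, was at 374 and 986 CPM in the mesenchymal lineage, 2.63-fold higher (2.60 to 2.67), but 1.06-fold higher (1.03 to 1.09) in the epithelium. Dlk1 was 5.10-fold higher (4.996 to 5.21) in the mesenchymal lineage, and Meg3, a maternally expressed RNA, 6.62-fold higher (6.18 to 7.09) in the epithelium.

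The libraries differed in the sex of their embryos. Among kept cells thinned to 5000 UMIs, a Y-linked UMI was found in 50.7%, 33.5%, 54.8% and 0.046% (0.006 to 0.166) in order of age, and a Xist UMI in 28.7%, 52.4%, 27.2% and 94.8%. Sex-linked differences between the E14.5 library and the others therefore carry the sex mix, and Agtr2 and Pof1b, named in the report, lie on the X chromosome.

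Globin counts in kept cells other than erythroid-like cells gave embryonic shares of 78.5%, 65.95%, 35.3% and 19.8% in order of age.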
